A study of Homo sapiens with 17 samples.

How the data were processed

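The authors deposited a table of estimated counts per gene, quantified from the reads, and a table of signal, the counts normalized between libraries, for each design. Per the submitters' processing notes, reads were quantified with Salmon (no version given) on hg38 and normalized with DESeq 1.28.1. The annotation and the strand setting are not stated. Per the labels, RNA was extracted with Trizol and libraries were made from 0.5 µg of total RNA with a TruSeq kit for sequencing on a NovaSeq instrument. The overexpression and empty vector lines were transfected with plasmid and kept in G-418 for 3 weeks. The knockout lines and their control received lentivirus with a guide RNA or a non-target guide and then puromycin for 3 days. The number after MDA-MB in the source names rises from sample to sample, and all samples were taken as MDA-MB-231, which the growth protocol names. Titles call this control "no guideRNA" and the knockouts "knockdown". The deposited counts are whole numbers, and each library's normalized counts equal its counts divided by a single factor (largest relative spread 1.1e-14), so the counts were analysed and the normalized counts were used in an alternative only.

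Of 58735 gene identifiers 58207 matched GENCODE release 44, from which symbols and coordinates were taken; 16615 of the genes tested in the knockout design and 16653 in the overexpression design matched. Library totals, in units of 1e6 counts, were 19.6, 22.1 and 21.3 for KO1, 19.1, 17.5 and 19.7 for KO4, and 20.9, 18.3 and 19.8 for the no guide control. In the other design they were 17.3 and 17.7 for the empty vector, 20.1, 20.1 and 19.9 for OE1, and 23.4, 22.6 and 20.2 for OE4. At these depths 3 counts in a library amount to 0.128 to 0.173 CPM, and smaller levels were not resolved.

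Each design was fitted on its own with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, a mean per line, robust quasi-likelihood dispersion and Benjamini-Hochberg adjustment over the genes of a contrast. A gene was called at an adjusted p below 0.05. Contrasts were each line against its control, the mean of the lines against the control, and the difference between the lines. The common biological coefficient of variation was 0.122 in the knockout and 0.157 in the overexpression design. Genes with 0 counts in a group are given as "at least" a fold, against a floor of 3 counts over that group, and genes with 1 to 10 counts as a ratio with its 95% counting interval. Fitted changes of such genes are kept for the mean of the lines, for the line differences listed at the end and for leave-outs, and are imprecise. Against the empty vector no change is given where a line compared has 0 counts or every line has 10 or fewer. Under the RLE factors of edgeR the median of all genes moved by at most 0.0149, and no named gene changed direction.

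Gene lists, 52 of them, were fixed before the files were seen, and the 20 described with their genes for the knockout and 13 for the overexpression lines were chosen after the values were seen. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of at least 5 measured genes. Alternatives were a correlation estimated per list and fry. Camera called 31 lists in the mean of the knockout lines, 6 with estimated correlations, and fry called 44; in the mean of the overexpression lines these were 15, 0 and 13. Counts of called list members use the adjustment over all genes, and those "adjusted over the list alone" use the p-values of the list's own genes.

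Genes were named by a rule fixed before the files were seen. It took NOP16, and per design the 10 largest rises and falls of the mean of the lines among protein-coding or long noncoding genes called the same way in both lines, with 5 CPM or more in the higher group and every library on the same side of every control library. It added 3 genes per direction and line, and up to 4 members of smallest adjusted p per described list, or the 2 of highest level if none was called. Last came 5 genes per direction that went oppositely in the designs or differed between lines. Genes that moved the same way against both controls, ranked by the smaller of the 2 changes, and the chromosome 9 neighbours CDKN2B, MTAP and FOCAD were chosen after their values were seen. Some genes that the rule picked, and 1 of the 12 listed markers, are not reported here, and no other gene took their place; they stayed in the tests and list counts. Sex-linked marker genes were left out of the printed tables and of naming, not of the tests.

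The pipeline was tested on simulated data with 200 genes changed 2-fold or 4-fold. For the mean of the knockout lines it found 71 of 97 genes (73.2%) changed 2-fold and 90 of 93 (96.8%) changed 4-fold among 16280 genes tested, with 13 false calls. For the mean of the overexpression lines it found 66 of 94 (70.2%) and 83 of 95 (87.4%) among 15932, with 7 false calls, and the differences between lines, where nothing was changed, gave 0 calls. No pairing of libraries by replicate number was used.

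Alternatives changed 1 setting at a time: DESeq2 1.42.0, RLE factors, no filter on low counts, a filter of 1 CPM and a 2-fold limit. Others were limma-trend on log2 of the deposited normalized counts plus 1, a fit of each line and its control only, a 2-group fit, and each library left out in turn. Added after seeing the data were the empty vector in place of the no guide control, from raw counts of all 17 libraries scaled together, a fit without the 233 genes seen only in the no guide control, a block on column numbers for OE1, and 20 simulations of unchanged knockout and overexpression lines against the same empty vector libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

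Each design has 1 control line, and each knockout or overexpression line is a separately derived population, so the p-values measure the spread between replicate samples of a line and not between independent lines. The empty vector has 2 libraries, with columns numbered 2 and 3 where the titles say replicate 1 and 2. The comparison of knockout lines with the empty vector crosses tables processed separately, so control and table could not be separated. It also sets lentivirus and 3 days of puromycin against plasmid and 3 weeks of G-418. Delivery, drug and selection time therefore enter every such value and could not be separated either. Counts of paralog families (SPANX, MAGE, PAGE and MT1 genes) and of overlapping genes (ARL10 with NOP16, the readthrough PPAN-P2RY11) depend on how the quantification shared reads, and NOP16 counts in OE1 and OE4 include the coding sequence of the transgene.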

Results

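The data are RNA-seq gene counts of cells taken as MDA-MB-231, the line named in the labelled growth protocol and an established triple-negative breast cancer cell line, after CRISPR knockout or plasmid overexpression of NOP16, a nucleolar protein that takes part in assembly of the large ribosomal subunit. The knockout design holds 3 libraries each of the bulk lines KO1 and KO4, made with different guides, and 3 of a no guide control. The overexpression design holds 3 libraries each of the stable lines OE1 and OE4 and 2 of an empty vector line. Library totals ran from 17297210 to 23405036 counts. Changes below are log2 fold changes, with standard errors (SE) where given, and levels are counts per 1e6 (CPM).

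NOP16 itself moved as the labels say in every library. It stood at 13.1, 11.4 and 11.3 CPM in the KO1 libraries and at 19.6, 20.3 and 18.8 CPM in the KO4 libraries, against 42.0, 40.4 and 40.2 CPM in the no guide control. These are changes of -1.78 (SE 0.09, edgeR adjusted p = 7.47e-08) in KO1 and -1.06 (SE 0.09, edgeR adjusted p = 6.17e-06) in KO4. KO1 lay below KO4 by a tested difference of -0.71 (SE 0.09, edgeR adjusted p = 0.000695). The overexpression libraries held 49.7, 61.2 and 55.9 CPM in OE1 and 56.0, 55.0 and 57.7 CPM in OE4, against 34.6 and 30.7 CPM in the empty vector libraries. The rises were 0.77 (SE 0.11, edgeR adjusted p = 0.00896) in OE1 and 0.78 (SE 0.11, edgeR adjusted p = 0.00546) in OE4, with no called difference between these lines (-0.02, edgeR adjusted p = 0.964). The gene lies on chromosome 5 from 176383946 to 176388927 on the minus strand of hg38, inside the span of ARL10 on the plus strand (176365487 to 176401865). The strand setting of the counting is not given. A CRISPR indel need not change mRNA level, and NOP16 protein was not measured here.

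**Figure D1:**
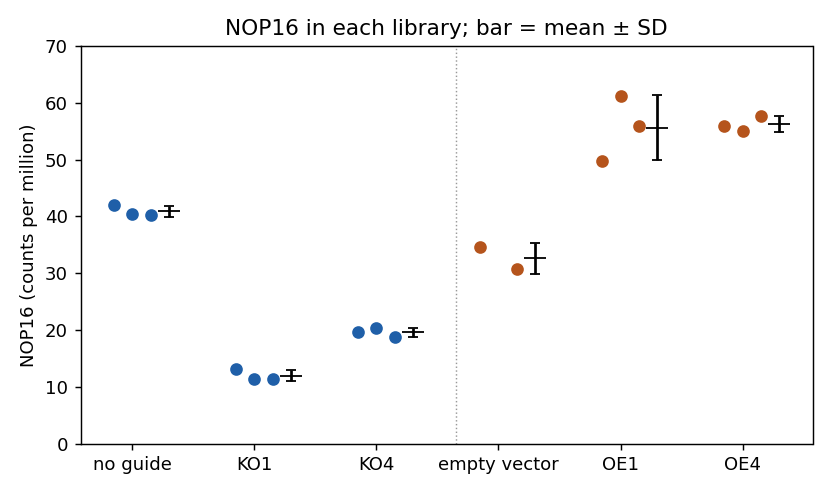
NOP16 level (vertical axis, CPM) in each of the 17 libraries (points) by line (horizontal axis), with the mean and standard deviation of each line as a bar. The dotted line parts the separately processed designs. All 6 knockout libraries lie between 11.3 and 20.3 CPM, under the no guide control (40.2 to 42.0 CPM), and all 6 overexpression libraries lie between 49.7 and 61.2 CPM, over the empty vector (30.7 and 34.6 CPM).

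Against the no guide control, both knockout lines held more mRNA for the collagenase MMP1 and the cytokine IL24, and less for genes of mitosis, DNA replication and cholesterol synthesis. HOX genes and other developmental regulators that were present in the no guide control lay near 0 counts in both lines. The edgeR test called 8427 of 16722 genes in KO1 (3932 higher, 4495 lower) and 5268 in KO4 (2483 higher, 2785 lower), of which 2414 and 1303 moved at least 2-fold. The same direction was called in both lines for 4788 genes (2230 higher, 2558 lower), where independent calls would share 584 and 749. The fold changes of the lines correlated across genes with a Pearson r of 0.914 and a Spearman rho of 0.829, although genes are not independent replicates. In 20 simulations of unchanged lines against the same 3 controls, r averaged 0.506 and no gene was called in both lines. Part of the excess in correlation and overlap may come from the shared controls. Their replicate spread gave 0.0495 of the measured covariance of 1.56 (difference 1.51). The simulations start from the control mean, so RNA held only by the no guide control would enter both lines alike and lie within that difference. How much of the difference such RNA gave was not measured. The libraries of the no guide control stood apart on the principal component that carried 64.8% of the variance (82.5 to 88.7, against -52.5 to -31.3 for the knockout libraries). With the empty vector libraries as control in their place, 7244 genes were called in KO1 and 4239 in KO4. This choice was made after seeing the data and crosses separately processed tables and different delivery and selection. Of the 2230 genes higher in both lines 851 were also higher against the empty vector (79 were lower), and of the 2558 lower genes 765 were also lower (64 were higher). The comparisons with the no guide control and with the empty vector share the knockout libraries, which favours calls in the same direction by construction.

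The largest differences were genes read in the no guide control and almost absent from KO1 and KO4. IRS4, an insulin receptor substrate on chromosome X (108719946 to 108736563), stood at 144 CPM (SD 19.3) in the control against 3 counts in all KO1 libraries together and 1 in KO4, a ratio of 3009.7 (95% counting interval 1029.9 to 14594.5) and of 8061.5 (1446.9 to 318413). Genes with no count in either knockout line were lower at least 347-fold in KO1 and 309.9-fold in KO4 for KLHL9, a ubiquitin ligase adaptor, and 298-fold and 266-fold for SMO, the Hedgehog signal transducer. The bounds were 300.2-fold and 268-fold for HOXA9, 272-fold and 243-fold for HOXA5, and 222-fold and 199-fold for the zinc finger gene ZNF711. HOXD13 was lower at least 597-fold in KO1 and by a ratio of 1599.7 (287 to 63183) in KO4. CDKN2A, which encodes the cell cycle inhibitor p16, was lower by a ratio of 750.1 (257 to 3638) in KO1 and at least 669.7-fold in KO4. The neuronal gene DPYSL5 was lower by a ratio of 1382 (248 to 54568) in KO1 and at least 411-fold in KO4. LIN28B, a regulator of let-7 microRNAs, was lower by a ratio of 1230.4 (221 to 48598) and at least 366-fold. Fitted changes of genes with so few counts move with the library left out. In the mean of the lines IRS4 went from -11.96 to -12.94 without KO4 replicate 2 and HOXD13 from -11.18 to -12.16 without the same library. CDKN2A went from -10.92 to -12.44 without KO1 replicate 2, DPYSL5 from -10.86 to -11.77 without KO1 replicate 1 and LIN28B from -10.69 to -11.59 without KO1 replicate 3. In the single lines IRS4 was -12.16 without KO1 replicate 2 (KO1, -11.38) and -14.50 without KO4 replicate 2 (KO4, -12.54).

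The same genes were near 0 in the empty vector and overexpression libraries. Over all genes, 233 reached 1 CPM in all 3 no guide control libraries and stayed under 0.5 CPM in each of the other 14 libraries, together 2043 CPM. The reverse held for 0 genes and no other line had more than 4 genes of its own. Of 12 markers of kidney packaging cells of the HEK293 kind listed before the files were seen, 8 were among these genes, 2 (CRMP1 among them) were present in every library, and 2 did not reach 1 CPM in the control. Markers of fibroblasts (0 of 12), blood cells (0 of 15) and endothelial cells (0 of 11) were not among them. On the short arm of chromosome 9, neighbouring genes of the CDKN2A region showed it too. CDKN2A (21967752 to 21995301) had 2129 counts in the control and 4 in the other 14 libraries, CDKN2B (22002903 to 22009305) 136 and 0, MTAP (21802636 to 21937651) 2113 and 146, and KLHL9 (21329665 to 21335404) 985 and 4. FOCAD (20658309 to 20995955), farther along the arm, had 713 and 809.

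**Figure D2:**
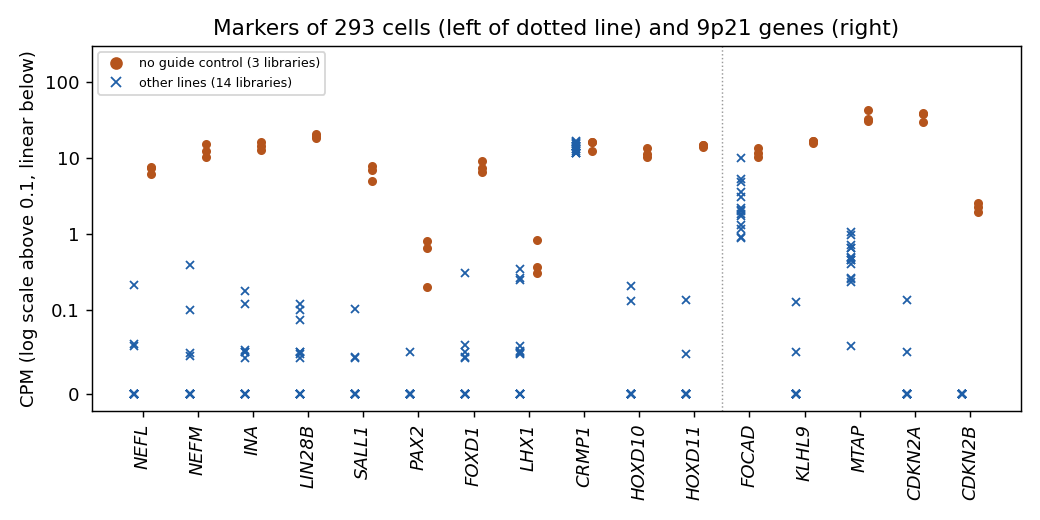
Level of 11 of the 12 markers of HEK293 cells (left of the dotted line) and 5 genes of the CDKN2A region (right) in CPM on an axis that is logarithmic above 0.1 and linear below. Circles are the 3 no guide control libraries and crosses the other 14 libraries. LIN28B, for example, lies between 18.2 and 20.6 CPM in the control and at most at 0.119 CPM elsewhere, while CRMP1 lies between 11.6 and 16.7 CPM in all 17 libraries.

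Developmental transcription factor genes of the kind that carries H3K27me3 in other tissues were mostly lower in the knockout lines. Of 55 measured members 47 fell and 4 rose in the mean of the lines, the same counts adjusted over the list alone, with a median of -4.14 (-3.76 with genes at 0 set to the floor). Members near 0 counts in both knockout lines passed the filter on low counts only through the no guide control. Their falls were fixed by that filter, and they enter these counts and the camera results of this list and of the HEK293 markers below. HOXD13 is described above, ZIC2 fell by 2.38 (45.1 CPM in the control, 8.25 in KO1, 9.14 in KO4) and HOXB9 by 1.51. The T-box gene TBX3 was lower by a ratio of 157 (72.2 to 428) in KO1 and of 421 (117 to 3476) in KO4. The camera test called the list (adjusted p = 1.49e-20, and adjusted p = 0.00101 with an estimated correlation). The HEK293 markers, 9 of 10 measured ones lower and also 9 adjusted over the list alone, had a median of -9.16 (-7.40 at the floor) with camera adjusted p = 1.06e-07 and adjusted p = 0.0258 with an estimated correlation. Among them the neurofilament genes INA and NEFM were lower at least 305-fold and by a ratio of 807 (145 to 31856) in KO1, and the HOX gene HOXD11 at least 279-fold in KO4. In the mean of the lines INA went from -10.20 to -11.18 without KO4 replicate 1 and NEFM from -10.08 to -10.96 without KO1 replicate 2. Against the empty vector libraries neither list was called: the medians were 0.00 (camera adjusted p = 0.815) and -0.01 (camera adjusted p = 0.747). Of 59 developmental genes in that fit 7 were higher and 6 lower in KO1, and 4 higher and 2 lower in KO4. The filter of that fit included the no guide control, so genes read only there were kept. For such genes this comparison cannot show a change. There HOXB9 read -0.16 and was not called, and TBX3 and HOXD11 had too few counts in every line compared for a change to be given.

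Genes that drive cell division were lower in both knockout lines. Of 51 mitosis genes 45 fell and none rose in the mean of the lines (46 adjusted over the list alone), with a median of -0.47. Cyclin A2 (CCNA2), which carries cells through S phase into mitosis, went from 206 CPM (SD 7.41) in the control to 87.4 (SD 3.61) in KO1 and 153 (SD 4.98) in KO4, a mean change of -0.84 (SE 0.04, edgeR adjusted p = 1.05e-07). The mitotic kinesin KIF20A fell by 0.93, the mitotic kinase PLK1 by 0.75 and the spindle protein CKAP2 by 0.75. Of 47 genes of S phase and DNA replication 41 fell (42 adjusted over the list alone), median -0.51. Among them were the phosphatase CDC25A (-1.25), and the helicase subunits MCM6 (-1.07) and MCM2 (-0.86). Camera called mitosis (adjusted p = 1.67e-12) and S phase (adjusted p = 1.72e-12), with adjusted p = 0.0388 with an estimated correlation for each. In KO4 alone the mitosis median of -0.21 was called by camera (adjusted p = 3.44e-05) but not in the other setting (adjusted p = 0.109 with an estimated correlation). The control libraries of this comparison are those that held 8 of the 12 listed HEK293 markers. With the empty vector as control the medians were -0.67 for mitosis (camera adjusted p = 1.58e-26) and -0.44 for S phase (camera adjusted p = 6.63e-11). Mitosis genes of the no guide control itself lay below those of the empty vector (-0.23, camera adjusted p = 2.65e-07; adjusted p = 0.0182 with an estimated correlation), so part of that -0.67 is a difference between the controls.

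Cholesterol synthesis fell as a pathway. Of 25 genes of cholesterol synthesis and its regulator SREBP2 24 fell and 1 rose, the same adjusted over the list alone, with a median of -1.02. INSIG1, the sterol sensor partner of SCAP, went from 221 CPM (SD 13.0003) in the control to 54.3 (SD 0.16) in KO1 and 91.0 (SD 7.23) in KO4 (-1.65, SE 0.06, edgeR adjusted p = 2.81e-09). The synthase HMGCS1 fell by 1.59 and the last enzyme of the pathway, DHCR7, by 1.46. The camera test called the list (adjusted p = 4.35e-12), a call lost when the correlation between its genes was estimated (adjusted p = 0.104 with an estimated correlation). Against the empty vector, whose libraries lack the 8 markers of HEK293 cells seen in the no guide control, the median was -0.79 (camera adjusted p = 6.94e-12, and adjusted p = 0.0351 with an estimated correlation). In these genes the no guide control itself lay above the empty vector (0.28, camera adjusted p = 0.00256; adjusted p = 0.347 with an estimated correlation), so part of the -1.02 is a difference between the controls.

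In the mean of the knockout lines against the no guide control, the largest rises among the named genes were those of MMP1 and IL24. MMP1, an interstitial collagenase on chromosome 11 (102789401 to 102798160), went from 9.24 CPM (SD 1.39) to 217 (SD 7.52) in KO1 and 87.8 (SD 3.40) in KO4 (mean 3.89, SE 0.09, edgeR adjusted p = 1.48e-10). IL24, a cytokine of the interleukin 10 family, went from 2.49 CPM (SD 0.66) to 54.4 (SD 1.81) and 20.4 (SD 1.54) (3.74, SE 0.14, edgeR adjusted p = 7.95e-09). The secretory chaperone SCG5 rose by 2.99, the lipase ADTRP by 2.92, the estrogen receptor gene ESR2 by 2.67 and the axon guidance gene DRAXIN by 2.55. Smaller rises were those of the kinase DGKI by 2.28, the phosphatase PTPRR by 2.21, the noncoding LINC00973 by 2.17 and the surface peptidase DPP4 by 2.08. In KO4 the axonemal dynein gene DNAH7 had the largest rise (4.02, SE 1.04, edgeR adjusted p = 0.0146), which rested on KO4 replicate 2: without that library it was 2.45 and not called. Without replicate 3 of the no guide control DNAH7 was 5.06 and the mean rise of ESR2 was 3.27. These 10 genes of the mean also rose against the empty vector, which lacks 8 HEK293 markers seen in the no guide control, by 1.61 for MMP1, 2.75 for IL24, 1.23 for ADTRP, 1.45 for DGKI and LINC00973, and 3.35 to 3.97 for the others.

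Genes of ribosome production, the process NOP16 serves, were modestly higher, mostly in KO1. Of 54 assembly factors of the large subunit 27 rose and 9 fell (27 and 10 adjusted over the list alone), median 0.13. Of 58 for the small subunit 24 rose and 8 fell (25 and 9 adjusted over the list alone), median 0.15. The helicase DDX10 rose by 1.63, the large subunit factors PAK1IP1 by 0.81, WDR74 by 0.74 and EIF6 by 0.59, and the small subunit factors UTP4 by 0.64 and AATF by 0.60. RRP1B fell by 0.57 and HEATR1 by 0.92. Camera called both lists (adjusted p = 0.0121 and 0.00216; adjusted p = 0.12 and adjusted p = 0.0659 with an estimated correlation). Ribosomal protein genes leaned the same way. For the large subunit 23 of 45 rose and 2 fell (25 and 2 adjusted over the list alone, median 0.19), and for the small subunit 14 of 32 rose and 4 fell (15 and 4 adjusted over the list alone, median 0.21). RPL28 rose by 0.66, RPL10A by 0.44, RPL19 by 0.36, RPS18 by 0.42, RPS10 by 0.40, and RPS16 by 0.32, whereas RPL4 fell by 0.32. Camera adjusted p was 0.000303 and 0.0116, lost as adjusted p = 0.522 and adjusted p = 0.611 with an estimated correlation. Host genes of small nucleolar RNAs rose most, 12 of 16 with none lower (12 adjusted over the list alone, median 0.69). SNHG8 rose by 1.51, SNHG1 by 1.31, GAS5 by 1.29 and SNHG7 by 1.09 (camera for the list, adjusted p = 3.63e-05; adjusted p = 0.309 with an estimated correlation). In KO4 alone camera called neither the assembly factors (medians 0.05 and 0.06, adjusted p = 0.236 and 0.111) nor the ribosomal proteins (0.06 and 0.07, adjusted p = 0.116 and 0.404). Against the empty vector, which lacks those 8 HEK293 markers, the medians were 0.24 and 0.22 for the assembly factors, 0.54 and 0.50 for the ribosomal proteins and 0.80 for the host genes. In KO4 alone they were 0.13 and 0.10 for the assembly factors and 0.38 and 0.37 for the ribosomal proteins there, all called by camera (adjusted p = 0.00639, 0.0214, 4.46e-13 and 7.14e-10). With an estimated correlation all 4 calls were lost (adjusted p = 0.11, 0.154, 0.195 and 0.256). The no guide control itself lay above the empty vector in the ribosomal proteins (0.31 and 0.30). RRP1B (0.04), HEATR1 (0.06) and RPL4 (0.22) turned sign, of which RPL4 was called.

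Nuclear genes for mitochondrial proteins shared this direction, and transcripts of the mitochondrial genome did not (1 of 15 higher and 9 lower, also adjusted over the list alone, median -0.20, camera adjusted p = 0.172; -0.14 against the empty vector, camera adjusted p = 0.526). Of 67 mitochondrial ribosomal protein genes 43 rose and 3 fell (45 and 3 adjusted over the list alone), median 0.23. MRPL34 was at 0.93, MRPL36 at 0.92, MRPL1 at 0.70 and MRPS10 at 0.55 (camera for the list, adjusted p = 3.02e-08; adjusted p = 0.307 with an estimated correlation). Of 59 nuclear genes of oxidative phosphorylation 31 rose and 3 fell (33 and 4 adjusted over the list alone), median 0.25. The cytochrome oxidase subunits COX6B1 and COX8A rose by 0.61 and 0.40, the complex I subunit NDUFS8 by 0.50 and the ATP synthase subunit ATP5PD by 0.42. The list was called by camera (adjusted p = 0.000128; adjusted p = 0.536 with an estimated correlation; in KO4 alone 0.11 and not called, camera adjusted p = 0.07). Against the empty vector libraries, without those 8 HEK293 markers, the medians were 0.45 and 0.40 (0.27 for oxidative phosphorylation in KO4 alone, camera adjusted p = 3.62e-07, lost as adjusted p = 0.4 with an estimated correlation), and MRPS10 at 0.09 was not called. In oxidative phosphorylation genes the no guide control itself lay above the empty vector (0.18, camera adjusted p = 0.0103; adjusted p = 0.838 with an estimated correlation), so part of the 0.40 is a difference between the controls.

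Genes of NF-kB, AP-1 and interferon signalling and metallothioneins were also higher. NF-kB targets and cytokines rose for 16 of 33 and fell for 1 (17 and 1 adjusted over the list alone), median 0.57. The survival gene BIRC3 was at 0.94, the signalling adaptor TRAF1 at 1.21 and IER3 at 1.20 beside IL24 (camera for the list, adjusted p = 1.44e-05; adjusted p = 0.0659 with an estimated correlation). AP-1 and immediate early genes rose for 22 of 34 and fell for 3 (22 and 3 adjusted over the list alone), median 0.41. PHLDA1 was at 1.39, the ERK phosphatase DUSP6 at 0.90, the AP-1 subunit FOSL1 at 0.79 and IER2 at 0.76 (camera for the list, adjusted p = 3.73e-05; adjusted p = 0.147 with an estimated correlation). Interferon-stimulated genes rose for 24 of 48 and fell for 2, as they did adjusted over the list alone, median 0.21. RIGI, a sensor of viral RNA, was at 0.68, ISG15 at 0.67 and UBE2L6 at 0.62, while USP18, which removes ISG15 from proteins, fell by 1.24 (camera for the list, adjusted p = 0.000393; adjusted p = 0.0388 with an estimated correlation). Metallothioneins and their list rose for 5 of 6 (5 adjusted over the list alone), median 1.06. The metal-binding MT1X rose by 1.89, MT2A by 1.25 and MT1E by 1.00, and the zinc exporter SLC30A1 by 0.23 (camera for the list, adjusted p = 0.000808; adjusted p = 0.0659 with an estimated correlation). The 8 HEK293 markers seen only in the no guide control are absent from the empty vector, against which the medians were 0.73 for NF-kB, 0.41 for AP-1, 0.15 for interferon and 0.51 for metallothioneins. In AP-1 genes the no guide control itself lay below the empty vector (-0.34, camera adjusted p = 0.00572; adjusted p = 0.23 with an estimated correlation). In that comparison IER3 (0.19), FOSL1 (0.13) and RIGI (0.06) were not called, and DUSP6 (-0.12) and USP18 (0.29) turned sign.

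Other lists moved less evenly. Of 26 endoplasmic reticulum chaperone and unfolded protein response genes 18 fell and 2 rose, also adjusted over the list alone, median -0.38. The transcription factor XBP1 fell by 0.82 and the disulfide isomerases PDIA4 by 0.54 and PDIA6 by 0.50, while the stress sensor ERN1 rose by 1.64 (camera for the list, adjusted p = 0.000334; adjusted p = 0.0555 with an estimated correlation; median -0.24 against the empty vector, where those 8 HEK293 markers are missing). The Polycomb complex PRC2, which writes H3K27me3, was not called as a list (3 of 12 higher and 4 lower, also adjusted over the list alone, median -0.03, camera adjusted p = 0.668). Its catalytic subunit EZH2 fell by 0.50 and RBBP4 by 0.71, while PHF1 rose by 0.44 and JARID2 by 0.40. In the comparison with the empty vector PHF1 (0.11) was not called and JARID2 (-0.08) turned sign. There no PRC2 gene was higher in either line. In KO1 6 of 12 were lower (median -0.13, camera adjusted p = 0.107). In KO4 3 were lower and camera called the list (median -0.14, camera adjusted p = 0.0438), a call lost as adjusted p = 0.177 with an estimated correlation. MYC and its core targets went both ways (14 of 45 higher, 19 lower; 14 and 21 adjusted over the list alone; median -0.11, camera adjusted p = 0.261). The folate carrier SLC19A1 was at -4.33, PLK1 at -0.75, the chaperonin HSPD1 at -0.53 and ODC1, the enzyme of polyamine synthesis, at 0.78. Targets of p53, which MDA-MB-231 carries in mutant form, did so too (13 of 32 higher, 10 lower, also adjusted over the list alone, camera adjusted p = 0.62). The median was 0.06 and the mean -0.20. Camera pointed up where fry, which tests whether the genes of a list move on balance to a side without a comparison to other genes, pointed down. Among these CCNG1 fell by 1.44, SESN2 by 1.34 and the repair gene XPC by 0.90, and SERTAD1 rose by 1.36. HSPD1 (0.02) and SESN2 (0.12) turned sign against the empty vector.

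**Figure D3:**
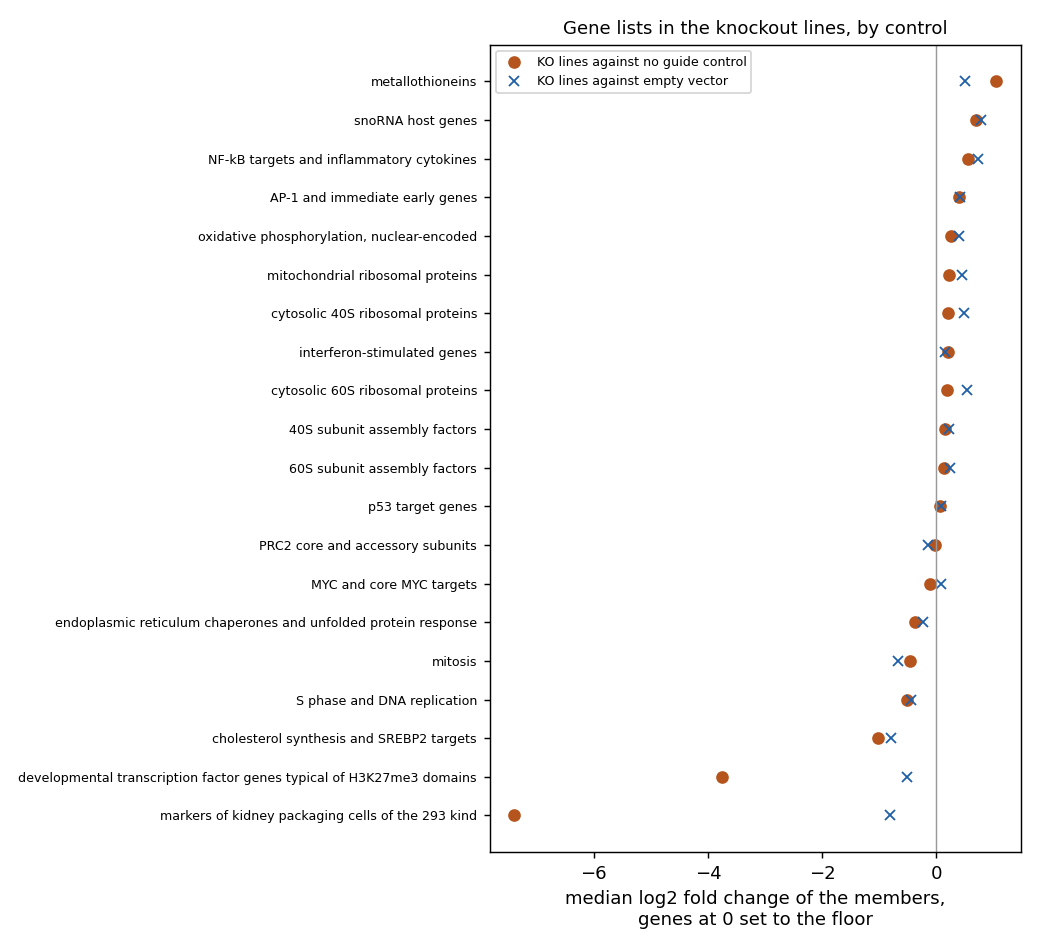
Median log2 fold change of the measured members of 20 gene lists (horizontal axis, genes at 0 counts set to the floor of 3 counts) in the mean of KO1 and KO4, against the no guide control (circles) and against the empty vector (crosses). The developmental and HEK293 lists move from -3.76 to -0.52 and from -7.40 to -0.81 between the controls, while cholesterol synthesis stays at -1.02 and -0.79 and snoRNA hosts at 0.69 and 0.79. The -0.52 and -0.81 come largely from the floor, which is 0.0478 CPM in KO1 and 0.0531 CPM in KO4 but 0.0883 CPM in the 2 empty vector libraries. Genes without counts in all of these lines therefore read as lower. Neither list was called against the empty vector.

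KO1, the line with less NOP16 mRNA, lay farther from the control than KO4 in many of these groups. A direct test of KO1 against KO4 called 2309 genes, 1035 higher and 1274 lower in KO1, of which 167 differed at least 2-fold. In KO1 48 of 51 mitosis genes were lower than in KO4 (49 adjusted over the list alone), median -0.55 (camera adjusted p = 8.80e-34, and adjusted p = 0.011 with an estimated correlation). So were 19 of 25 cholesterol genes (21 lower and 1 higher adjusted over the list alone), median -0.52 (camera adjusted p = 2.82e-13; adjusted p = 0.116 with an estimated correlation). The polarity gene LLGL2 differed by -1.65 (SE 0.20, edgeR adjusted p = 0.000461), the oxytocin receptor OXTR by -1.77 and the antisense RNA GAS6-AS1 by -1.91. IL24 (1.41) and MMP1 (1.30) were higher in KO1, as was the ceramidase ASAH2 (1.90), the RNA sensor TLR7 (2.50) and the glycosylation gene ALG14 (2.10). The calls of ALG14 and TLR7 were lost in 5 of 9 leave-outs each and that of the readthrough PPAN-P2RY11 (-1.57) in 4. TLR7 was 1.52 without KO1 replicate 1, and PPAN-P2RY11 -2.19. The count of called genes fell to 1080 without KO1 replicate 1.

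Fewer genes were called in both overexpression lines than in both knockout lines. The designs differ in control line, number of control libraries and spread, so these counts do not compare the size of the responses. Against the empty vector, PAGE5, a cancer-testis gene of chromosome X (55220346 to 55224108), went from 0.32 CPM (SD 0.05) to 5.68 (SD 0.74) in OE1 and 4.99 (SD 0.44) in OE4 (4.02, SE 0.30, edgeR adjusted p = 0.000317). The sorting receptor SORCS3 rose by 3.63, the nuclear pore gene NUP210 by 2.82, the sperm protein gene SPANXB1 by 2.45 and INHBA, a subunit of activin, by 2.30. The chloride channel ANO2 rose by 3.46, the focal adhesion gene TNS1 by 3.15, LINC01929 by 2.66 and the teneurin TENM2 by 2.51, and these 4 moved with the empty vector library used. Without empty vector library 2 and then without 3, ANO2 was 4.63 and 2.84, TNS1 2.34 and 5.22, LINC01929 2.21 and 3.34, and TENM2 2.01 and 3.29. The call of TNS1 was lost in 1 of 8 leave-outs. In OE1 the scaffold gene FRMPD4 was higher by a ratio of 62.6 (21.4 to 304). In OE4 the cancer-testis gene MAGEA6 was higher at least 87.1-fold, the antisense RNA DNAJC27-AS1 by a ratio of 186 (33.3 to 7337) and the noncoding UCA1 by 3.97. FRMPD4 read 9.83 and 4.95 without empty vector library 2 and 3, DNAJC27-AS1 6.397 and 9.83, and UCA1 3.47 and 4.76. FRMPD4 and DNAJC27-AS1 each lost their call in 1 leave-out. NUP210 also stood above the empty vector (1.32 CPM) in lines without NOP16 overexpression. It was at 98.96 CPM in the no guide control, 8.13 CPM in KO1 and 18.3 CPM in KO4. DNAJC27-AS1 had 1 count in the empty vector but 435 in KO1 and 168 in KO4. For this pair overexpression and a departure of the empty vector line were not separated. SORCS3 went the other way, with 29 counts in the empty vector, 2 in KO1 and 0 in KO4.

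Genes that fell in both overexpression lines included SHH, the Hedgehog ligand, from 44.2 CPM (SD 4.87) to 16.02 (SD 3.31) in OE1 and 6.28 (SD 0.69) in OE4 (-2.14, SE 0.15, edgeR adjusted p = 0.000297). The immunoglobulin domain gene VSTM4 fell by 3.63, the calcium channel TRPV4 by 2.94, the thrombin receptor gene F2RL3 by 1.98, SETBP1 by 1.99, the phosphodiesterase PDE8B by 1.83 and the protease inhibitor TIMP4 by 1.76. The no guide control, without NOP16 overexpression, was also low in SHH (10.1 CPM), F2RL3 (4.01 CPM) and SETBP1 (1.33 CPM). In these 3 genes overexpression and a departure of the empty vector line were not separated. VSTM4 stood at 4.66 CPM there, above OE1 (0.565 CPM) and OE4 (0.599 CPM). ALPK3 (-6.72), ARL10 (-3.09), PRDM6 (-1.86) and, in OE4, SGSM1 (-4.02) each moved with 1 empty vector library. Without library 2 and then without 3 they were -7.69 and -1.82 for ALPK3, -3.83 and -1.48 for ARL10, -1.08 and -2.36 for PRDM6, and -4.88 and -1.50 for SGSM1. In OE1 the semaphorin SEMA5A was lowest after ALPK3 (-5.12, SE 0.98, edgeR adjusted p = 0.0293), a call lost in 5 of 8 leave-outs. Of the leave-outs, 7 ended that of SGSM1, 5 that of PRDM6, 2 that of ARL10 and 1 each those of SETBP1 and of ALPK3 in the mean. In OE1 the call of ALPK3 (-6.32) was lost in 7 and in OE4 (-7.13, lower by a ratio of 143, 72.8 to 332, and -8.38 without OE4 replicate 1) in 4.

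In all, edgeR called 431 of 16760 genes in OE1 (178 higher, 253 lower) and 743 in OE4 (349 higher, 394 lower), with 176 and 232 of them at least 2-fold. In both lines 95 genes rose and 100 fell, 195 in all, where independent calls would share 3.71 and 5.95. Across genes the fold changes of the lines correlated with a Pearson r of 0.767 and a Spearman rho of 0.652, against 0.637 in simulations of unchanged lines with these controls, where at most 1 gene was called in both. Part of the excess may come from the shared controls. Their replicate spread gave 0.111 of the measured covariance of 0.504 (difference 0.394), and a departure of the empty vector line itself would enter that difference. The empty vector libraries stood apart from each other (chi-square per degree of freedom 29.2, against 5.52 to 16.7 for other replicate pairs; 5.48% and 7.71% of counts from the mitochondrial genome). Without empty vector library 2 the calls rose to 1504 in OE1, 2459 in OE4 and 1045 in both, and without OE4 replicate 2 those in both fell to 69.

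Extracellular matrix and mesenchymal genes were lower in the overexpression lines than in the empty vector. Fibronectin (FN1) went from 559 CPM (SD 83.2) to 275 (SD 24.1) in OE1 and 244 (SD 22.4) in OE4 (-1.11, SE 0.10, edgeR adjusted p = 0.000671). The collagen genes COL6A3 (-1.02) and COL5A1 (-0.55) and the proteoglycan GPC1 (-0.93) fell too. Of 45 matrix genes 12 fell and 1 rose (18 and 3 adjusted over the list alone), median -0.27 (camera adjusted p = 0.00109; adjusted p = 0.467 with an estimated correlation). Of 27 mesenchymal genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), median -0.29 (camera adjusted p = 0.000624; adjusted p = 0.333 with an estimated correlation). COL6A2 fell in the mean (-0.59), a call lost in 5 of 8 leave-outs, but went down in OE1 (-2.38) and up in OE4 (1.19). Protease and invasion genes fell for 11 of 27 and rose for 3 (14 and 3 adjusted over the list alone), median -0.26. TIMP2, an inhibitor of metalloproteases, fell by 0.42 and ADAM19 by 0.73, while the chemokine receptor CXCR4 rose by 1.25 and MMP1 by 1.14 (camera for the list, adjusted p = 0.0061; adjusted p = 0.333 with an estimated correlation). Hypoxia genes fell for 5 of 30 and rose for 2 (12 and 2 adjusted over the list alone), median -0.18. NDRG1 was at -0.86, the angiogenic factor VEGFA at -0.66, the mitophagy receptor BNIP3L at -0.50 and the peptide hormone ADM at 0.78 (camera for the list, adjusted p = 0.000766; adjusted p = 0.333 with an estimated correlation). Without empty vector library 3 the rise of ADM was 0.59 and not called. The no guide control, without NOP16 overexpression, also lay below the empty vector in these lists: -0.51 for proteases (camera adjusted p = 3.13e-07), -0.28 for mesenchymal genes (camera adjusted p = 0.0777), -0.16 for hypoxia (camera adjusted p = 0.0714) and -0.15 for the matrix (camera adjusted p = 0.466). The knockout lines also lay below the empty vector in the matrix list, by -0.58 in KO1 and -0.34 in KO4 (camera adjusted p = 0.00215 and 0.0214; adjusted p = 0.12 and 0.195 with an estimated correlation). Mesenchymal genes were at -0.26 and -0.28 there (camera adjusted p = 0.0974 and 0.042). Hypoxia genes (-0.24 and -0.23) and proteases (0.06 and -0.14) were not called. Overexpression and a departure of the empty vector line were not separated for these falls.

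Ribosomal genes leaned upward, mostly in OE4, but in ribosomal proteins the no guide control, without NOP16 overexpression, lay above the empty vector by more than the mean of these lines did (0.31 for large and 0.30 for small subunit proteins, camera adjusted p = 7.00e-07 and 3.12e-06; adjusted p = 0.438 with an estimated correlation for each). Overexpression and a departure of the empty vector line were therefore not separated for these proteins. Of 45 large subunit proteins 5 rose and none fell (19 adjusted over the list alone), median 0.17, and of 32 small subunit proteins 6 rose (15 adjusted over the list alone), median 0.23. RPL35A was at 0.60, RPL36 at 0.55, RPL22 at 0.47, RPL13A at 0.31, RPS26 at 0.50, RPS25 at 0.33, RPS2 at 0.29 and RPS13 at 0.27, each call lost in 3 to 7 of 8 leave-outs. Camera adjusted p was 1.68e-06 and 1.79e-05, and adjusted p = 0.638 with an estimated correlation for each. Among 54 large subunit assembly factors NOP2 alone rose (0.53), also adjusted over the list alone, with a list median of 0.09 (camera adjusted p = 0.0298; adjusted p = 0.467 with an estimated correlation). Among 16 snoRNA hosts SNHG29 rose (0.55; 9 adjusted over the list alone), median 0.55 (camera adjusted p = 5.76e-05; adjusted p = 0.591 with an estimated correlation). In the hosts the no guide control lay above the empty vector by less and without a call (0.12, camera adjusted p = 0.622), and by as much and without a call in the assembly factors (0.09, camera adjusted p = 0.366). Nuclear oxidative phosphorylation genes rose for 3 of 59 (6 higher and 2 lower adjusted over the list alone), median 0.19. NDUFA1 was at 0.69, COX5B at 0.43 and COX8A at 0.33, calls lost in 5 to 7 leave-outs (camera for the list, adjusted p = 1.79e-05; adjusted p = 0.638 with an estimated correlation). In this list the no guide control lay above the empty vector by 0.18 (camera adjusted p = 0.0103; adjusted p = 0.838 with an estimated correlation).

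Cancer-testis genes rose for 3 of 8 (5 adjusted over the list alone), median 1.06 (0.94 in OE1, or 0.13 there with genes at 0 set to the floor). The genes were PAGE5, MAGEC2 (0.78) and MAGEC1 (0.50), the calls of the last pair lost in 7 and 8 leave-outs. Camera called the list (adjusted p = 2.56e-07), a call lost as adjusted p = 0.333 with an estimated correlation. The lines differed by more than these mean rises: OE1 minus OE4 was 1.61 for MAGEC2 and -2.43 for MAGEC1, so neither mean describes both lines. Interferon-stimulated genes rose for 8 of 48 and fell for 3 (8 and 8 adjusted over the list alone) with no call as a list (median -0.00, mean 0.05, camera adjusted p = 0.834). In the mean of the lines RSAD2 was at 1.10, IFIT2 at 0.74, IFIT1 at 0.67 and ISG15 at 0.56. OE1 lay below OE4 in each (OE1 minus OE4 -2.40, -0.48, -0.72 and -0.90). No PRC2 subunit was called (median -0.07, camera adjusted p = 0.583; 1 higher and 2 lower adjusted over the list alone), with RBBP7 at -0.27 and PHF19 at 0.10. RBBP7 was called without empty vector library 3 (-0.37). Of 26 developmental transcription factors IRX5 (1.06) and MEIS1 (1.55) rose (2 higher and 1 lower adjusted over the list alone; median 0.15, camera adjusted p = 0.172), each call lost in 6 leave-outs.

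**Figure D4:**
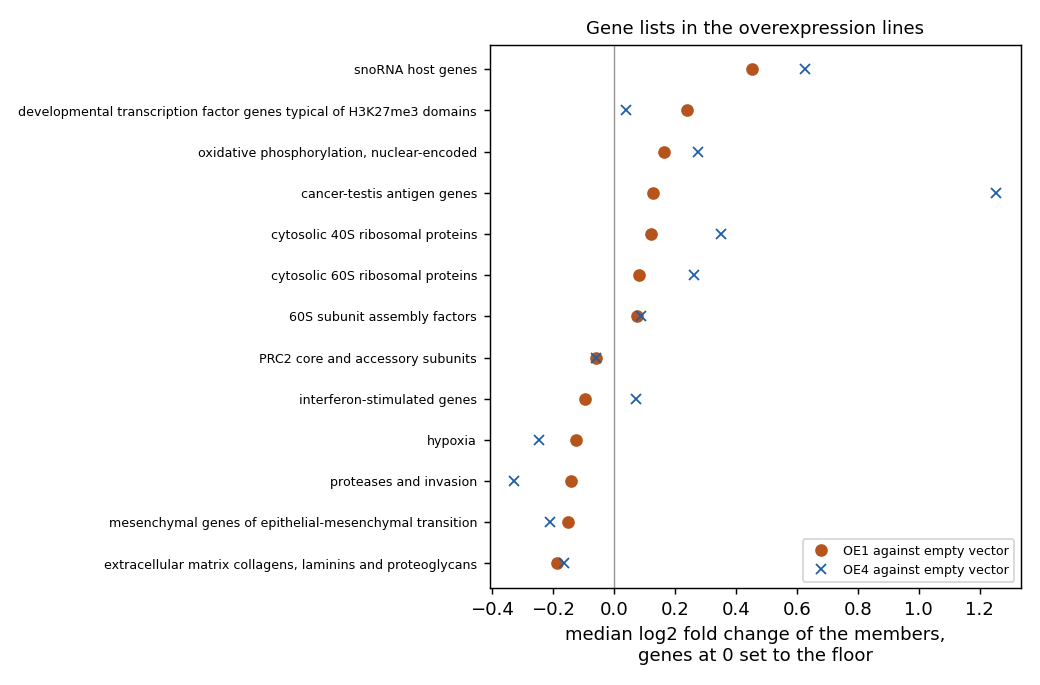
Median log2 fold change of the measured members of 13 gene lists (horizontal axis, genes at 0 counts set to the floor of 3 counts) in OE1 (circles) and OE4 (crosses) against the empty vector. Large and small subunit ribosomal proteins lie at 0.08 and 0.12 in OE1 and at 0.26 and 0.35 in OE4, and matrix genes at -0.19 and -0.16.

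The overexpression lines differed from each other in 440 genes, 194 higher and 246 lower in OE1, of which 128 differed at least 2-fold. MAGEA6 was read in OE4 (7.65 CPM, SD 0.82) with 2 counts in OE1 (lower by a ratio of 234, 64.7 to 1929; edgeR adjusted p = 0.000409). The chemokine CX3CL1 (-3.73), COL6A2 (-3.57), UCA1 (-3.55) and the adipokine RARRES2 (-3.37) were lower in OE1 than in OE4. Higher were FRMPD4 (3.43), SORCS3 (1.81), the neuronal surface gene SLITRK1 (1.79), IGSF3 (1.78) and the phosphodiesterase PDE2A (1.70). FRMPD4 lost its call in 4 leave-outs (4.38 without OE4 replicate 1) and PDE2A in 2. Ribosomal proteins were lower in OE1 for 9 of 45 and 6 of 32 genes (23 and 24 adjusted over the list alone), medians -0.26 and -0.26 (camera adjusted p = 7.60e-13 and 8.33e-12; adjusted p = 0.401 and adjusted p = 0.42 with an estimated correlation). Interferon-stimulated genes were lower in OE1 for 7 of 48 and higher for 1 (11 and 1 adjusted over the list alone), median -0.16, with RSAD2 at -2.40 and ISG15 at -0.90 (camera adjusted p = 0.00317; adjusted p = 0.301 with an estimated correlation). The cancer-testis list had a median of 0.07 but a mean of -1.84 and no camera call (adjusted p = 0.22). The mesenchymal list had a median of 0.11 and a mean of -0.06 with camera pointing up and fry down, and the matrix list a median of 0.06 and a mean of -0.01 with both pointing down. Without OE4 replicate 3 the lines differed in 114 genes, and without empty vector library 3 in 901.

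Few genes went in opposite directions in the designs. Among 15926 genes tested in both, 33 rose in both knockout lines and fell in both overexpression lines (13.5 expected for independent calls, Fisher exact adjusted p = 1.62e-06). The reverse held for 19 (11.4 expected, Fisher exact adjusted p = 0.0474), among them NOP16 itself, whose directions the design set. The test was not run without NOP16. The same direction was shared by 15 higher and 14 lower genes (11.8 and 12.9975 expected, Fisher exact adjusted p = 0.458 and 0.764). LTBP1, which anchors latent TGF-beta in the matrix, rose by 1.19 in the knockout lines (1.09 against the empty vector) and fell by 0.85 with overexpression. The thrombin receptor F2RL3 (0.93 and -1.98), the cystatin CST1 (0.93 and -1.71), SECTM1 (1.02 and -0.88) and the deubiquitinase OTUB2 (0.99 and -0.80) did likewise. NUP210 (-3.03 and 2.82), the asparaginase ASRGL1 (-3.76 and 3.44), HYKK (-3.27; higher by a ratio of 6.95, 3.37 to 17.3, in OE1 and of 5.57, 2.70 to 13.9, in OE4), the synaptic gene NRXN3 (lower by a ratio of 147, 40.7 to 1213, in KO1; higher by 13.6, 7.39 to 28.3, in OE1) and TMEM98 (-4.47; at least 12.1-fold and 8.55-fold higher in OE1 and OE4) went the other way. Over all genes the mean changes of the designs had a Pearson r of -0.02 and a Spearman rho of 0.03, and genes are not independent replicates. With the knockout lines set against the empty vector too, in 1 fit of all 17 libraries, r was 0.692, below the mean of 0.776 in 20 simulations of unchanged lines that share this control. The covariance was 0.68, against 0.144 in the simulations (difference 0.536). A departure of the empty vector line itself would enter that difference. The no guide control, whose libraries alone held 8 of the 12 listed HEK293 markers, enters each of these knockout values. With the empty vector as control only 4 of the 33 and 5 of the 19 were called the same way, while of the genes that shared a direction in both designs 12 of the 15 and 11 of the 14 were. Sharing the empty vector favours calls in the same direction by construction, so these counts do not separate the explanations. F2RL3 (-0.94), SECTM1 (-0.64), NUP210 (3.20), ASRGL1 (1.20) and HYKK (ratios of 1.63, 0.79 to 4.04, and 2.58, 1.25 to 6.41) turned sign, with calls for F2RL3, SECTM1 and NUP210. TMEM98, with no count in the empty vector, was higher there at least 4.34-fold in KO1 and 2.81-fold in KO4, and CST1 (0.27) was not called. Without KO4 replicate 2 the fall of HYKK in the knockout lines was -3.88. In the overexpression lines ASRGL1 was 4.51 and 2.85 without empty vector library 2 and 3, and the calls of HYKK and SECTM1 were lost in 6 and 3 leave-outs.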

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

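The 7 explanations tested below, and the other splits of the libraries, were chosen only after the results they address had been seen. The genes and lists of the next 3 paragraphs were brought up by a direct test of the difference between the lines of a design, and the patterns after them by comparisons with the controls.

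In the knockout design 71 named genes and 14 lists differed between KO1 and KO4. Values are KO1 minus KO4 (log2), with standard errors of 0.04 to 0.65. Lower in KO1 were GAS6-AS1 -1.91, OXTR -1.77, LLGL2 -1.65, PPAN-P2RY11 -1.57, NUP210 -1.19, ADGRB2 -1.12, KIF20A -1.09, FHL1 -0.97, PHGDH -0.90, PABPC4L -0.82, DHCR7 -0.81, CCNA2 -0.80, PLK1 -0.76, INSIG1 -0.74, HMGCS1 -0.74, NOP16 -0.71, CCNG1 -0.52, CDC25A -0.41, CKAP2 -0.40, EZH2 -0.38, PDIA4 -0.38, MCM6 -0.32, PDIA6 -0.32 and MCM2 -0.23. Higher in KO1 were TLR7 2.50, ALG14 2.10, ASAH2 1.90, IL24 1.41, MMP1 1.30, ADTRP 1.13, SCG5 1.12, SNHG1 0.87, SNHG8 0.87, GAS5 0.86, MT1X 0.83, PPP1R15A 0.78, TFPI2 0.78, LINC00973 0.76, SNHG7 0.76, MT2A 0.71, SERTAD1 0.66, ATP6V0D2 0.62, DRAXIN 0.61, IER2 0.51, PHLDA1 0.49, DDX10 0.46, MRPL36 0.46, PAK1IP1 0.45, COX6B1 0.43, LTBP1 0.41, WDR74 0.41, MT1E 0.41, CST1 0.41, OTUB2 0.40, IER3 0.37, MRPL34 0.35, FOSL1 0.32, NDUFS8 0.30, RPL10A 0.29, ODC1 0.28, AATF 0.28, ATP5PD 0.28, RPS18 0.28, UTP4 0.27, RPL28 0.26, RPL19 0.25, EIF6 0.24, MRPS10 0.22, DUSP6 0.19, RPS16 0.19 and RPS10 0.16.

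List medians lower in KO1 were mitosis -0.55, cholesterol synthesis -0.52, S phase -0.23 and endoplasmic reticulum chaperones -0.20. Higher were snoRNA hosts 0.49, nuclear oxidative phosphorylation 0.27, large subunit ribosomal proteins 0.25, metallothioneins 0.24, small subunit ribosomal proteins 0.23, mitochondrial ribosomal proteins 0.22, small subunit assembly factors 0.18, AP-1 genes 0.17, p53 targets 0.13 and large subunit assembly factors 0.10. With an estimated correlation camera kept the call of 3 of these 14 lists: mitosis (adjusted p = 0.011), small subunit assembly factors (adjusted p = 0.0235) and large subunit assembly factors (adjusted p = 0.0461).

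In the overexpression design 26 named genes and 6 lists differed between OE1 and OE4. Lower in OE1 were MAGEA6 -7.62 (a fit on 2 counts in OE1), CX3CL1 -3.73, COL6A2 -3.57, UCA1 -3.55, RARRES2 -3.37, MAGEC1 -2.43, RSAD2 -2.40, ISG15 -0.90, IFIT1 -0.72, IFIT2 -0.48, COX8A -0.40, COL5A1 -0.37 and RPS2 -0.30. Higher were FRMPD4 3.43, SORCS3 1.81, SLITRK1 1.79, IGSF3 1.78, PDE2A 1.70, MAGEC2 1.61, SHH 1.35, SPANXB1 1.25, INHBA 1.22, LTBP1 0.68, COL6A3 0.66, CST1 0.62 and TIMP2 0.33. List medians were -0.26 for large and -0.26 for small subunit ribosomal proteins, -0.16 for interferon-stimulated genes, -0.0860 for nuclear oxidative phosphorylation, 0.19 for developmental transcription factors and 0.0840 for proteases and invasion. Camera called none of the 6 lists with an estimated correlation (adjusted p = 0.301 to 0.705).

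Genes near 0 in both knockout lines and present in the no guide control form the largest pattern. Silencing by loss of NOP16 is argued against, since only 1.03% of the 291 such genes reached 1 CPM in both empty vector libraries, where NOP16 was intact. Another cell line in place of MDA-MB-231 is argued against too: 0 genes present in the other 14 libraries were missing from the control. RNA from cells of the HEK293 kind within the no guide control libraries would show their markers there and nowhere else, and 8 of the 12 listed markers did so (2, CRMP1 among them, were present in all libraries, PAX2 and LHX1 stayed under 1 CPM), with IRS4 at 144 CPM, NID1 at 39.1 CPM and CDKN2A at 35.9 CPM. This remains a hypothesis: lentivirus is commonly packaged in such cells, but puromycin would remove untransduced ones, and the step at which such RNA entered was not tested.

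The lower mitosis, S phase and cholesterol genes in both knockout lines were set against RNA of other cells in the control. The smallest of the 3 falls against the empty vector was still -0.44, which that explanation as the whole cause would not give. The empty vector also differs from the knockout lines in delivery, drug and selection time, so this comparison does not exclude it. The no guide control itself lay 0.23 below the empty vector in mitosis genes, so the fall against the empty vector holds a difference between the controls there. A graded response to NOP16 is open: all 3 medians were lower in KO1, the line with less NOP16 mRNA, and the one nearest 0 was -0.23, but it would also raise them with overexpression, where the medians were 0.039 for S phase, -0.020 for mitosis and -0.025 for cholesterol and none was called. With 2 lines, the NOP16 level and any other difference between the lines cannot be told apart.

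Of the 52 genes called in opposite directions in the designs, 15 had both controls between the knockout and overexpression lines, as a graded response to NOP16 would give, and NOP16 itself is among them. In 21 the no guide control lay outside the range of the other 5 lines, as RNA of other cells in that control would give. These explanations cannot be told apart for the set, since the no guide control enters every knockout value and each design has 1 control line.

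Other splits of the libraries were compared with the real one. The real split was the 1 with most genes in every case. Other splits mix libraries of different lines within a group, which raises the fitted spread and lowers their counts by construction. Libraries of a line are also not independent lines, so no conclusion is drawn from the lower counts. For KO1 and KO4 against the control and for KO1 against KO4 only 10 splits exist, too few to judge: 8427, 5268 and 2309 genes for the real split, and at most 0, 0 and 1 for another. The same holds for OE1 against OE4, with 440 genes against at most 1 in 10 splits. The knockout libraries pooled against the control gave 6648 genes against at most 3030 in 84 splits. Genes called the same way in both knockout lines were 4788 against at most 4120 in 100 splits, which were the real one and random regroupings. The 4120 came from a split that keeps the 3 control libraries together.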

How the results depend on the processing

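NOP16 kept its direction and call in all 50 alternative values, and so did 2277 of the values of named genes. Of the others 13 turned sign, 165 lost their call (158 with a library left out, 7 with the empty vector as control) and 2 gained it. Leave-outs, which keep the control line, make up 1754 of the 2277. All 13 sign changes came with the empty vector as control, where 80 values kept direction and call. Genes given no change there, such as IRS4 and HOXD13, are not counted in that setting. Of the counts 114 stayed within 1.5 times the reported value and 73 moved, and all counts stayed so under RLE factors, the filter of 1 CPM and limma-trend. Unless named otherwise, the cause was not tested.

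Counts for OE1, OE4, their mean, their difference and both lines were 1006, 1463, 1336, 965 and 476 with DESeq2, and 1014, 1446, 1418, 914 and 500 with no filter on low counts. At a 2-fold limit they were 176, 232, 203, 128 and 73, and for the knockout design 2414, 1303, 1822, 167 and 1188, fewer by construction. With only the line and its control OE1 gave 94 and OE4 317 (fewer samples), and a 2-group fit gave 202 for the mean. Opposite genes were 96 with DESeq2, 85 with no filter, 7 at 2-fold and 21 with the empty vector as control. Without the genes seen only in the no guide control, KO1 gave 8201, KO4 4962, their mean 7684 and both lines 4511. Lists called with estimated correlations were 6 in KO1, 6 in KO4, 6 in their mean, 4 for their difference and 0 in each overexpression contrast, and fry called 44 in KO1 and 44 in KO4.

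With the empty vector as control these turned sign: JARID2 -0.0811, RRP1B 0.0438, HEATR1 0.0567, RPL4 0.22, HSPD1 0.0195, SESN2 0.12, USP18 0.29, DUSP6 -0.12, F2RL3 -0.94, SECTM1 -0.64, ASRGL1 1.20, NUP210 3.20 and HYKK 1.03. TMEM98, lower by 4.47 against the no guide control, turned sign as well (at least 4.34-fold higher in KO1 and 2.81-fold in KO4), but is given only as a bound and is not among the 13.

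With each library left out in turn, the ranges were 7361 to 8543 genes for KO1, 4429 to 5019 for KO4, 7008 to 7858 for their mean, 1080 to 2921 for their difference and 4083 to 4450 for both. For OE1 they were 142 to 1504, for OE4 206 to 2459, for their mean 240.0 to 2184, and for their difference 114 to 901. They were for both 69 to 1045, and for opposite genes 17 to 121, with the highest counts (but for the difference) without empty vector library 2; a lone empty vector library is then assumed to vary like the other groups. NOP16 ran from -1.84 to -1.72 in KO1, -1.10 to -1.03 in KO4, 0.69 to 0.86 in OE1 and 0.71 to 0.88 in OE4. A block on replicate number gave 8145 genes and a NOP16 change of -1.76 for KO1 against the no guide control. Residuals of KO1 and no guide control libraries of the same number correlated at 0.05, -0.02 and 0.02, so numbers do not pair them. By column number OE1 and OE4 libraries correlated at 0.08, 0.13 and 0.01, where a pairing was taken to need over 0.1 in every pair, and those of different number at -0.10 to 0.01. No paired analysis was possible by title number for OE1 because the empty vector columns are numbered 2 and 3 while their titles say 1 and 2. A block on the column numbers, added after seeing the data, leaves 1 residual degree of freedom and gave 87 genes and a NOP16 change of 0.85; it moved the count for OE1.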

Other observations

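Some genes moved the same way against both controls, a group chosen after seeing the data. Of the genes called in both knockout lines 851 were higher and 765 lower against the no guide control and the empty vector alike. Independent calls would share 243.4 and 292.9. The comparisons with these controls use the same knockout libraries, which favours calls in the same direction by construction. How much of the overlap this gave was not measured, so the overlap is not a replication. PHGDH, the entry enzyme of serine synthesis, ranked first among the falls by the smaller of its 2 changes: from 114 CPM in the no guide control to 1.91 in KO1 and 3.58 in KO4 (-5.43, and -2.31 against the empty vector). The mitochondrial reductase MTARC1 (-2.71 and -2.19), the nucleosome-binding HMGN5 (-2.13 and -2.14), the adhesion gene EMB (-2.10 and -4.03), REEP1 (-2.28 and -1.98), the nuclear receptor NR2F1 (-1.72 and -2.35), ADGRB2 (-2.08 and -1.72), FHL1 (-3.09 and -1.72) and PABPC4L (-1.74 and -1.72) fell as well.

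Higher against both controls, beside the genes of the report, were PPP1R15A, which restarts translation after stress (2.00 and 2.03; 101 CPM in the no guide control, 529 in KO1, 307 in KO4), PTGS2, the inducible cyclooxygenase (2.06 and 2.74), the proton pump gene ATP6V0D2 (1.97 and 3.23) and the protease inhibitor TFPI2 (1.81 and 2.04). The no guide control and the empty vector themselves differed in 4858 genes, and in NOP16 by 0.31 (edgeR adjusted p = 0.0281).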
